A study of Mus musculus with 3 samples.

How the data were processed

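Expression was measured in 3 RNA pools of whole mouse embryos at 8.5 dpc, 1 normal and 2 from Dnmt3l mutant dams. Per the labels' protocols, RNA was extracted with Trizol, and biotin-labelled cRNA was made for Affymetrix arrays. The deposited values are array intensity values on a linear scale, 1 per probe set and array, and the submitters' processing notes name GCOS and MAS5 without versions or settings. From the values, the mean after trimming 2% at each end was 500 on every array, so each array had been scaled to the same trimmed mean, and nothing showed a further normalization between arrays. Such scaling assumes that total signal is alike in the pools, so a change in tissue makeup moves other genes the opposite way. Scanner files were not used here. Median signals were 143.6, 130.0 and 139.6 for the normal array and mutant arrays 1 and 2. Pearson's r of log2 values across probe sets, which are not independent replicates, was 0.932 and 0.934 between the normal array and mutants 1 and 2, and 0.963 between the mutants. The 3' to 5' signal ratio of the Actb control was 1.62, 1.24 and 1.43, and that of Gapdh was 0.93, 0.859 and 1.10.

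Of the 45101 probe sets, 64 Affymetrix controls were left out. Genes were named from the platform annotation that came with the files, in which 34945 of the 45037 probe sets left had 1 gene symbol, 932 had several and 9160 were not listed. No gene was named from a probe set with several symbols, and a gene measured only by such probe sets, or by none, was not analysed here. The mouse gene table of assembly GRCm38.p6 changed 0 symbols when they were looked up by gene identifier. It also brought older symbols on the gene lists up to date and gave the genes that neighbour Dnmt3l and those on the X chromosome. The deposited values name no genome build, so no coordinates are given.

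The pseudocount was 31.92, the median over arrays of each array's 20th percentile. A probe set was kept where the mean of the 2 group means of log2(signal + 31.92) was at or above the 40th percentile, which left 27022. Limma (version 3.58.1 in R 4.3.3) was fitted to the 3 arrays with lmFit and eBayes with a trend of variance on signal, two-sided, with Benjamini-Hochberg adjustment over kept probe sets and a threshold of 0.05. This left 1 residual degree of freedom, from the 2 mutant arrays, to which eBayes added 4.52 prior degrees of freedom. The 1 normal array is assumed to vary as the mutant arrays do, and the p-values cannot show whether it was typical of normal embryos. All adjusted p-values of single genes come from this limma fit. Counts of at least 2-fold change required a log2 ratio of 1 or more, in the same direction, in both mutant arrays.

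Before the data were examined, 27 gene lists were fixed from general knowledge. They cover imprinted genes by domain and allele, germline genes, DNA methylation machinery, embryonic erythroid, cardiac, neural, somite and tailbud, neural crest, 2 Hox groups, yolk sac endoderm, trophoblast, decidua and uterus, allantois and amnion, endothelial, gut endoderm, proliferation, p53 targets, hypoxia and glycolysis, integrated stress response, immediate early and heat shock, Y chromosome, Xist, Dnmt3l neighbours and reference genes. Each gene was represented by its brightest kept probe set, which gave 12913 genes. The 26 lists with 3 or more kept genes were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over those lists. At that setting a list's genes are taken as nearly independent. The p-values therefore leave out most variation that such genes share between pools. Camera with an estimated correlation and fry were run as alternatives. The estimated correlation and both of these tests rest on 1 residual degree of freedom. With an estimated correlation the lowest adjusted p was 0.476, shared by many lists. Fry gave adjusted p from 0.0433 (germline genes) to 0.843 (DNA methylation machinery). A list whose call was lost by them rests on the preset correlation. Fry tests whether a list's genes move on balance one way without setting them against other genes. Each list's median was also ranked among 10000 random lists of the same size matched on mean expression. A gene was said to rise or fall where it passed over all probe sets or adjusted over the list alone, as stated.

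Named genes followed a rule fixed before the data were examined. Dnmt3l came first. The imprinted lists and the sex chromosome lists gave up to 10 genes each by the smaller of the mutant arrays' log2 ratios, plus any gene that passed adjusted over the list alone. The array gave the 10 highest and 10 lowest genes by that measure among those that passed, filled from the rest where fewer passed. Every other list gave up to 4 genes. Genes named only in the last sections for other reasons were chosen after their values were seen.

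The scripts were tested on simulated data for the mutant against normal comparison, over 27022 probe sets, in 20 simulations with 200 changed probe sets each. All noise was drawn from the differences between the mutant arrays. Limma recovered 1.21% of probe sets changed by 2-fold, 29.7% of those changed 4-fold and 65.0% of those changed 8-fold. Changes near 2-fold were therefore mostly not detectable as single genes. Limma made 71.5 calls on average, of which 8.35 were false. More than 5% of the calls were thus false, although the threshold on adjusted p was 0.05. With no simulated effect it called 1.1 probe sets on average and 13 at most. For simulated lists of 20 genes, camera gave p under 0.05 in 5% with no shift and in 100% with a shift of 0.5. The noise was drawn separately for every probe set, so these lists held no correlation between genes. They do not show how camera behaves on lists of genes that vary together, such as those of 1 tissue. Alternatives fixed before the data were examined were other pseudocounts (15.96, 63.84 and 1), quantile normalization, cyclic loess, median centring, no filter and a filter at the 60th percentile, eBayes without a trend and with robust moderation, the mean of a gene's probe sets, the other set tests, and leaving out each mutant array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.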

Results

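Gene expression was measured in whole mouse embryos at 8.5 days post coitum (dpc) on 3 single-channel Affymetrix arrays, each hybridised with RNA from a pool of litter mates of both sexes. The normal group was 1 array, from 6 pooled C57Bl/6J embryos. The mutant group was 2 arrays that the labels call biological replicates, from 8 and 6 pooled embryos. The mutant embryos were heterozygous for Dnmt3l and were the offspring of homozygous mutant dams and wildtype sires, on a C57Bl/6J background. Dnmt3l is a cofactor of the de novo DNA methyltransferases that is needed in the growing oocyte to set maternal methylation imprints. The series title describes the mutants as deficient in maternal methylation, and the comparison asks which transcripts differ from normal embryos when those marks were not set. All 45101 probe sets had a signal on every array, with median signals of 144 on the normal array and 130 and 140 on mutant arrays 1 and 2. Because the normal group had no replicate, its spread was taken to equal that of the mutant arrays, and the number of arrays limited the precision of every value below. Log2 ratios compare log2(signal + 31.92) in the mutants with the normal array and understate the change of dim genes.

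Dnmt3l itself gave little information. Its probe set read 12.2 on the normal array and 183 and 14.3 on mutant arrays 1 and 2, and the filter on dim probe sets removed it. The embryos carried a wildtype paternal allele, and the position of the probes relative to the deleted part was not analysed here, so the probe set did not check the labels.

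Imprinted genes that are expressed from the paternal allele in maternally marked domains were higher in the mutants as a group. Of the 19 genes kept by the filter, 14 were higher in both mutant arrays, none was lower in both and 5 differed in sign. The median log2 ratio was 0.37 (0.34 in mutant 1 and 0.60 in mutant 2). Plagl1, a zinc finger transcription factor, rose from 3617 to 13333 ± 2646 (SD, n = 2), a log2 ratio of 1.86 (SE 0.21) with an adjusted p of 0.0408 over all probe sets. Adjusted over the list alone, 6 genes rose. Besides Plagl1 these were Impact, a regulator of translation (log2 ratio 1.24, SE 0.29), Zdbf2 (1.13, SE 0.30), the sarcoglycan gene Sgce (0.97, SE 0.22), Mcts2, a retrogene inside an intron of H13 (0.91, SE 0.23), and the zinc finger gene Peg3 (0.59, SE 0.13). Peg10, a gene derived from a retrotransposon, read 2.38 in mutant 1 and 0.85 in mutant 2, and did not pass (1.61, SE 0.63). Nnat (0.49), Inpp5f (0.46) and Mest (0.32) did not pass either. A dimmer probe set of Impact had the opposite sign, with a log2 ratio of -0.10, and the mean of its probe sets gave 0.42. The list's shift passed camera with a preset correlation (adjusted p = 1.66e-05). The call was lost with an estimated correlation (adjusted p = 0.476) and by fry (adjusted p = 0.141). Yolk sac endoderm genes were higher in the same arrays (median log2 ratio 2.80).

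Imprinted genes listed as expressed from the maternal allele in the same kind of domain were lower. The imprinted lists were fixed from general knowledge. Which allele gave each gene's signal in these whole embryos was not tested, so the falls below are falls of total signal. Of 25 genes measured, 17 were kept by the filter. Of these 17, 14 were lower in both mutant arrays and 2 were higher in both. Their median log2 ratio was -0.66 (-0.72 in mutant 1 and -0.65 in mutant 2), and it was -0.53 without the filter. Cdkn1c, a cyclin-dependent kinase inhibitor, fell from 3738 to 41.8 ± 13.4 (SD, n = 2), a log2 ratio of -5.69 (SE 0.32, adjusted p = 0.0111 over all probe sets). Its mutant signals, 32.3 and 51.3, lay near the pseudocount. Igf2r, the receptor that clears insulin-like growth factor 2, fell from 2932 to 321.5 ± 23.4 (SD, n = 2), a log2 ratio of -3.07 (SE 0.24, adjusted p = 0.0185), and its other measured probe set gave -2.70. Adjusted over the list alone, 8 genes fell. These included Phlda2, a regulator of placental growth (-2.93, SE 0.40), the growth factor receptor adaptor Grb10 (-3.53, SE 1.05) and H13, an intramembrane protease of signal peptides (-1.57, SE 0.26). Tssc4 (-0.92), Cd81 (-0.72) and Commd1 (-0.66) were the others. The size of the Grb10 value rested on 1 array, since mutant 1 read -2.14 and mutant 2 read -4.93. The mean of its probe sets gave -2.22. H13 had a dimmer probe set with the opposite sign (0.22), and the mean of its probe sets gave -0.90. Copg2 (-0.89), Tnfrsf23 (-0.66) and Tfpi2 (0.70) did not pass. The list passed camera with a preset correlation (adjusted p = 1.75e-08). It was lost with an estimated correlation (adjusted p = 0.476) and by fry (adjusted p = 0.133). In the same arrays, 54 cardiac, neural and somite genes had a median log2 ratio of -0.67, and the decidual gene Prl8a2 read -3.41.

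Domains that carry a paternal mark, which the mother's germline does not set, did not pass camera as a list. The median log2 ratio of the 6 genes measured was 0.05 (adjusted p = 0.0996 by camera with a preset correlation, and 0.476 with an estimated correlation), and the mean was 0.39. None passed over all probe sets, and adjusted over the list alone 2 genes rose. Dlk1, a Notch family ligand expressed from the paternal allele, rose from 4577 to 9774 ± 953.5 (SD, n = 2), a log2 ratio of 1.09 (SE 0.17). Rian, a noncoding RNA of the same domain that is expressed from the maternal allele, had a log2 ratio of 1.28 (SE 0.34). A pair of dimmer Rian probe sets had the opposite sign, with -0.47 and -0.32, and the mean of its probe sets gave 0.27. Igf2, the fetal growth factor, read 13550 and 13866 ± 43.5 (SD, n = 2), a log2 ratio of 0.03 (SE 0.13).

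**Figure D1:**
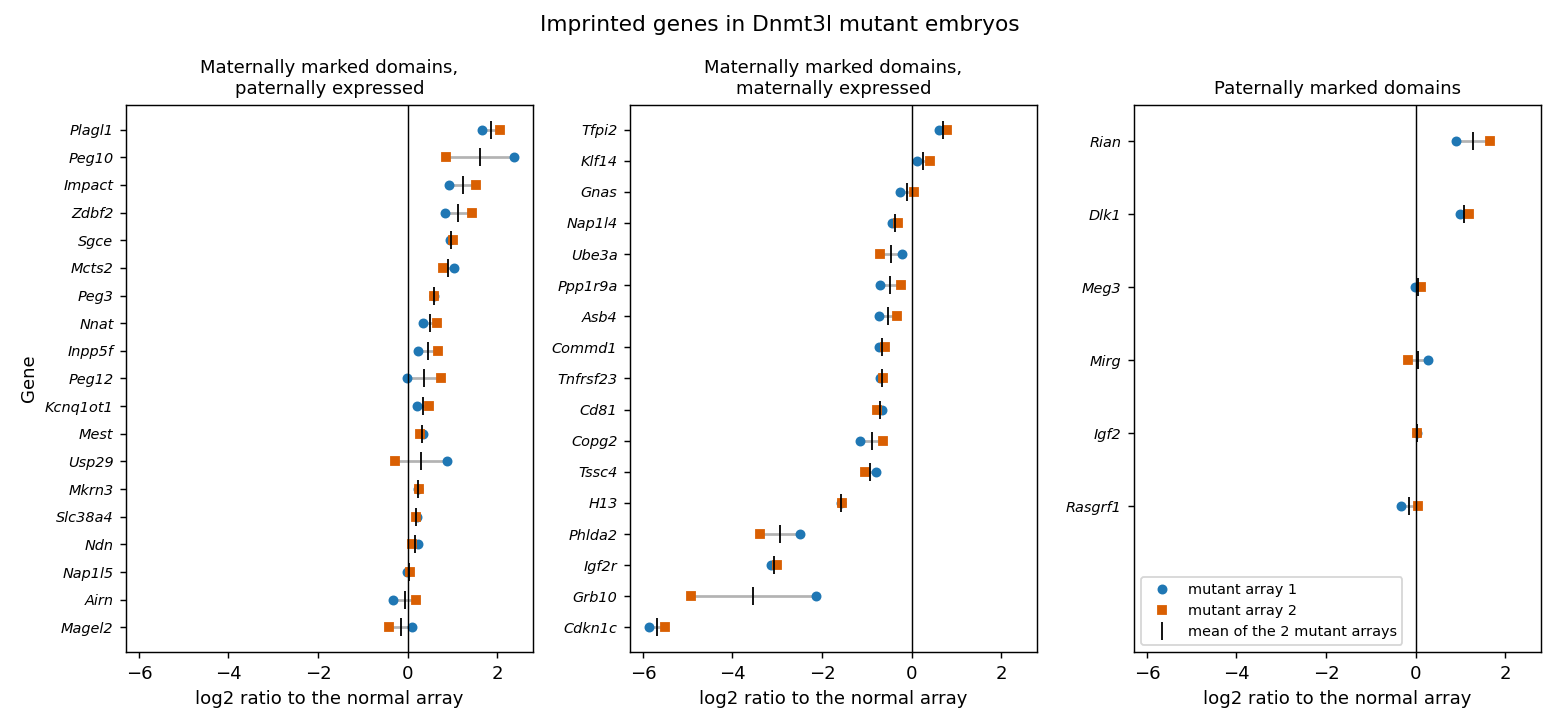
Log2 ratio of each mutant array to the normal array for every imprinted gene kept by the filter. The 3 panels are by the parental mark of the domain and the expressed allele as listed. Circles are mutant array 1, squares are mutant array 2 and ticks are their mean, and Cdkn1c, Igf2r, Phlda2 and Grb10 lie below -2 in both arrays.

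Over the whole array, far more probe sets rose than fell. Limma called 148 probe sets higher and 8 lower among the 27022 kept, which were 110 and 5 named genes. At an unadjusted p under 0.05 (limma) the 2 directions were near equal, with 1811 higher and 1853 lower. That balance depended on the scaling of the arrays. Median centring gave 2038 higher and 1560 lower, cyclic loess 2022 and 1650, and quantile normalization 1953 and 1778. By size alone, 694 probe sets were at least 2-fold higher and 514 at least 2-fold lower in both mutant arrays. Simulated arrays with no effect gave means of 178.4 and 178.7, and 1237 probe sets differed by 2-fold or more between the mutant arrays. Probe sets that the annotation does not list made up 52.3% of the 514 and 4.9% of the 694, against 14% of all kept. Each mutant array on its own gave 1102 and 1118 higher and 1581 and 1100 lower. The calls were lost (0 and 0) without the filter on dim probe sets, where 2423 higher and 2451 lower had an unadjusted p under 0.05. They were also lost (0 and 0) when the moderated variances were not fitted to signal, with 1641 and 1814 at that unadjusted p, so every single gene call over all probe sets rested on both choices.

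The genes named next were, among those that passed, the 10 with the largest rise in the less changed mutant array. Hebp1, a heme-binding protein, rose from 82.2 to 1679 ± 57.6 (SD, n = 2), a log2 ratio of 3.91 (SE 0.24, adjusted p = 0.0111). The calcium-binding protein gene S100g had a log2 ratio of 4.06 (SE 0.33), and Cap1, which acts on the actin cytoskeleton, had 3.71 (SE 0.24). Apob and Apoa4, which code for lipoproteins, had 3.85 (SE 0.28, and 2.48 with the mean of probe sets) and 3.79 (SE 0.40), and the fibrinogen chain gene Fgb had 3.29 (SE 0.24). The others were 4933402E13Rik (3.72), the tight junction gene Cldn2 (3.31, and 2.32 with the mean of probe sets), the biliverdin reductase gene Blvrb and the carboxylesterase gene Ces2b. Blvrb read 26.3 on the normal array against 871 and 576, and Ces2b read 10.1 against 372 and 386. Both normal signals lay below the 20th percentile of that array (31.92), so the sizes of these 2 rises depend on the pseudocount, and Blvrb's log2 ratio ranged from 3.10 to 4.70 over the pseudocounts tried. Ces2b read 2.58 with a doubled pseudocount and had no value with either smaller one, because the filter then removed it. On the lower side only 4 of the genes named had passed. These were Cdkn1c and Igf2r, the decidual prolactin-family gene Prl8a2 (1376 against 101.3 ± 14.3, SD, n = 2, log2 ratio -3.41, SE 0.30) and LOC102631979 (-2.90, SE 0.32). The remaining 6 had the largest decreases in the less changed array among genes that did not pass over all probe sets. They were Phlda2, Grb10, Prap1, the microtubule-associated ubiquitin ligase gene Mid1 (-2.92, with -2.28 in mutant 1 and -3.56 in mutant 2), the centrosomal gene Wdr62 and the protease inhibitor gene Ctla2a (-1.85). Prap1 read 431 against 20.5 and 57.7, and Wdr62 263.5 against 36.8 and 28.1, so the sizes of these falls depend on the pseudocount too.

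**Figure D2:**
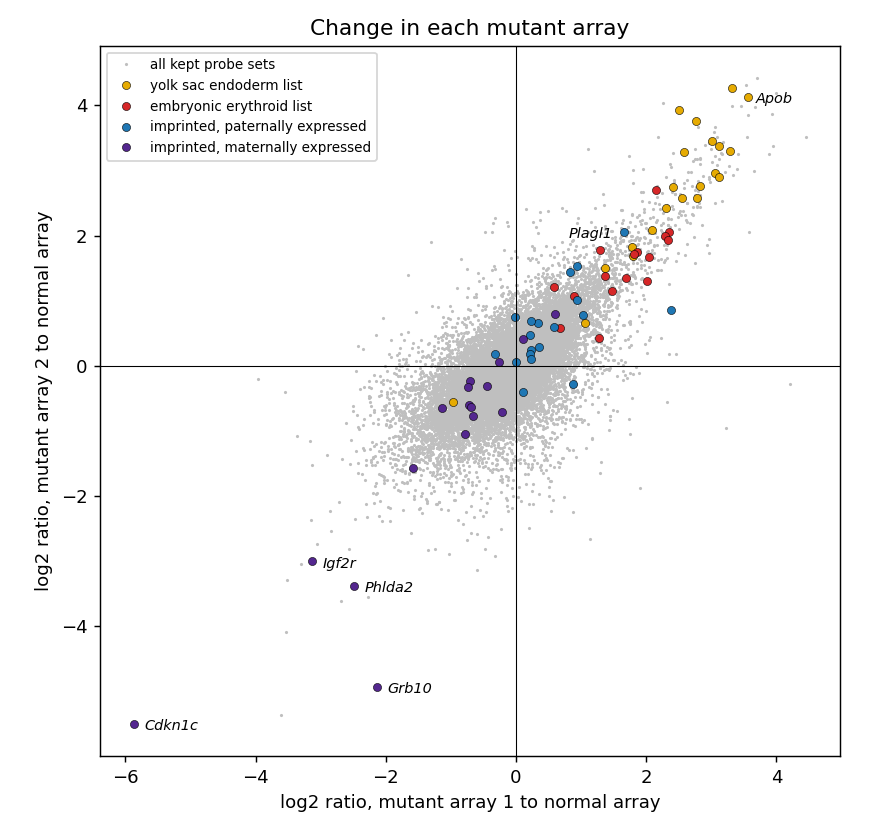
Log2 ratio to the normal array in mutant array 1 (x axis) against mutant array 2 (y axis), with 1 grey point per kept probe set and coloured points for 4 gene lists. Yolk sac endoderm genes lie at the upper right, and Cdkn1c, Igf2r, Phlda2 and Grb10 at the lower left.

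Genes of tissues outside the embryo proper and of blood were higher in the mutants. Yolk sac endoderm genes had a median log2 ratio of 2.80 over 21 genes (2.59 in mutant 1 and 2.77 in mutant 2), 16 rose over all probe sets and 20 rose adjusted over the list alone. Apob, Apoa4 and Fgb were among them, and Cubn, a receptor for protein uptake, rose from 1238 to 12053 ± 1521 (SD, n = 2), a log2 ratio of 3.25 (SE 0.18, adjusted p = 0.0111). Alb, the albumin gene, was the exception (-0.77, SE 0.38) and did not pass. Embryonic erythroid genes had a median of 1.60 over 16 genes, all higher in both arrays, with 3 rising over all probe sets and 14 adjusted over the list alone. Slc4a1, the red cell anion exchanger, had a log2 ratio of 2.43 (SE 0.30), the heme synthesis gene Alas2 and the transcription factor gene Klf1 each had 2.14, and Hemgn had 2.21. Of 6 trophoblast genes (median 0.96, 1.29 in mutant 1 and 0.71 in mutant 2), 1 rose over all probe sets and 3 rose adjusted over the list alone. These were the homeobox gene Esx1 (2.25, SE 0.28), Plac1 (1.76, SE 0.23) and Hand1 (1.35, SE 0.25), while Plet1 read -0.39 (0.52 with the mean of its probe sets) and did not pass. Without the filter on dim probe sets, the trophoblast median was 0.24 over the 11 genes measured and the list's call was lost (camera adjusted p = 0.145). The allantois and amnion list, which also holds Hand1, had a median of 0.79 over 8 genes (0.95 and 0.57). None of them passed over all probe sets, and adjusted over the list alone Hand1, Postn (1.99, SE 0.53, with 1.33 in mutant 1 and 2.64 in mutant 2) and Ahnak (1.03, SE 0.23) rose, while Tbx4 (1.20) did not pass. The 4 lists passed camera with a preset correlation, with adjusted p = 4.68e-33, 1.50e-18, 0.00425 and 0.00141 in the order given. The estimated correlations were 0.143, 0.0833, -0.2 and 0.143 in that order, against the preset 0.01. With an estimated correlation each list had an adjusted p of 0.476. By fry all 4 calls were lost, with adjusted p = 0.133, 0.133, 0.133 and 0.273 in that order.

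Genes of the embryo's own organs were lower as lists while no single gene passed. Cardiac genes had a median log2 ratio of -0.67 over 20 genes, with 15 lower in both arrays, but the arrays differed (-1.04 in mutant 1 and -0.22 in mutant 2). The cardiac troponin gene Tnnt2 read 4141 and 1929 ± 284 (SD, n = 2), a log2 ratio of -1.10 (SE 0.22, adjusted p = 0.134), and Tbx5 (-1.45), Tnni1 (-1.01) and Nkx2-5 (-0.94) read lower too. Neural genes had a median of -0.64 over 18 genes (-0.53 and -0.51), including Otx2 (-1.34), Pax3 (-1.26) and Sox1 (-1.17), while the early neuron gene Elavl3 read 1.01. Somite and tailbud genes had a median of -0.68 over 16 genes (-0.61 and -0.64), including Hes7 (-2.03, with -1.25 in mutant 1 and -2.81 in mutant 2), Fgf8 (-1.71), Tbx6 (-1.11) and Dll3 (-0.68). Hox genes of groups 1 to 5 had a median of -0.48 over 13 genes (-0.61 in mutant 1 and -0.19 in mutant 2), with Hoxb1 at -0.99, Hoxb3 at -0.94, Hoxd3 at -0.67 and Hoxb4 at -0.48. Groups 6 to 13 had a median of -0.45 over 13 genes (-0.52 and -0.47), which was -0.18 over the 20 genes measured without the filter and -0.68 with the stricter filter, with Hoxd9 at -0.96, Hoxa9 at -0.90, Hoxb9 at -0.89 and Hoxc6 at -0.80. The 5 lists passed camera with a preset correlation, with adjusted p = 1.66e-05, 3.45e-04, 1.66e-05, 0.00758 and 0.00724 in the order given. The estimated correlations were 0.326, 0.0588, -0.05, 0.0769 and -0.0769 in that order, against the preset 0.01. With an estimated correlation each list had an adjusted p of 0.476. By fry all 5 calls were lost, with adjusted p = 0.504, 0.371, 0.133, 0.315 and 0.208 in that order. Yolk sac endoderm genes moved the opposite way in the same arrays (median 2.80).

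Of the other tissue lists, endothelial and gut endoderm genes passed camera with a preset correlation, and both calls were lost with an estimated correlation (adjusted p = 0.613 and 0.476). Yolk sac endoderm genes were higher in the same arrays (median log2 ratio 2.80). Neural crest genes had a median of -0.20 over 15 genes and did not pass camera (adjusted p = 0.203), with Crabp1 at -0.89, Sox10 at -0.73, Foxd3 at -0.45 and Ednrb at 0.72. Endothelial genes had a median of 0.46 over 14 genes (0.32 in mutant 1 and 0.67 in mutant 2, camera adjusted p = 0.00834). No endothelial gene passed alone, and Pecam1 read 1.06, Cdh5 1.02, Sox7 0.86 and Erg 0.81. Gut endoderm genes had a median of 0.36 over 12 genes (camera adjusted p = 0.0324), and only Spink1, a trypsin inhibitor gene, rose (2.30, SE 0.21). Cldn6 (0.64), Epcam (0.61) and Pyy (-0.97) did not pass. Decidua and uterus genes, chosen to mark maternal tissue, had a median of -0.00198 over 9 genes, a mean of -0.25 and a camera adjusted p of 0.463. The sign of that median turned under other scalings of the arrays. Hoxa11 of this list is also on a Hox list. Prl8a2 fell, and Pgr (-0.62), Wnt4 (0.40) and Lum (1.57, SE 0.67, with 0.71 in mutant 1 and 2.43 in mutant 2) did not pass.

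**Figure D3:**
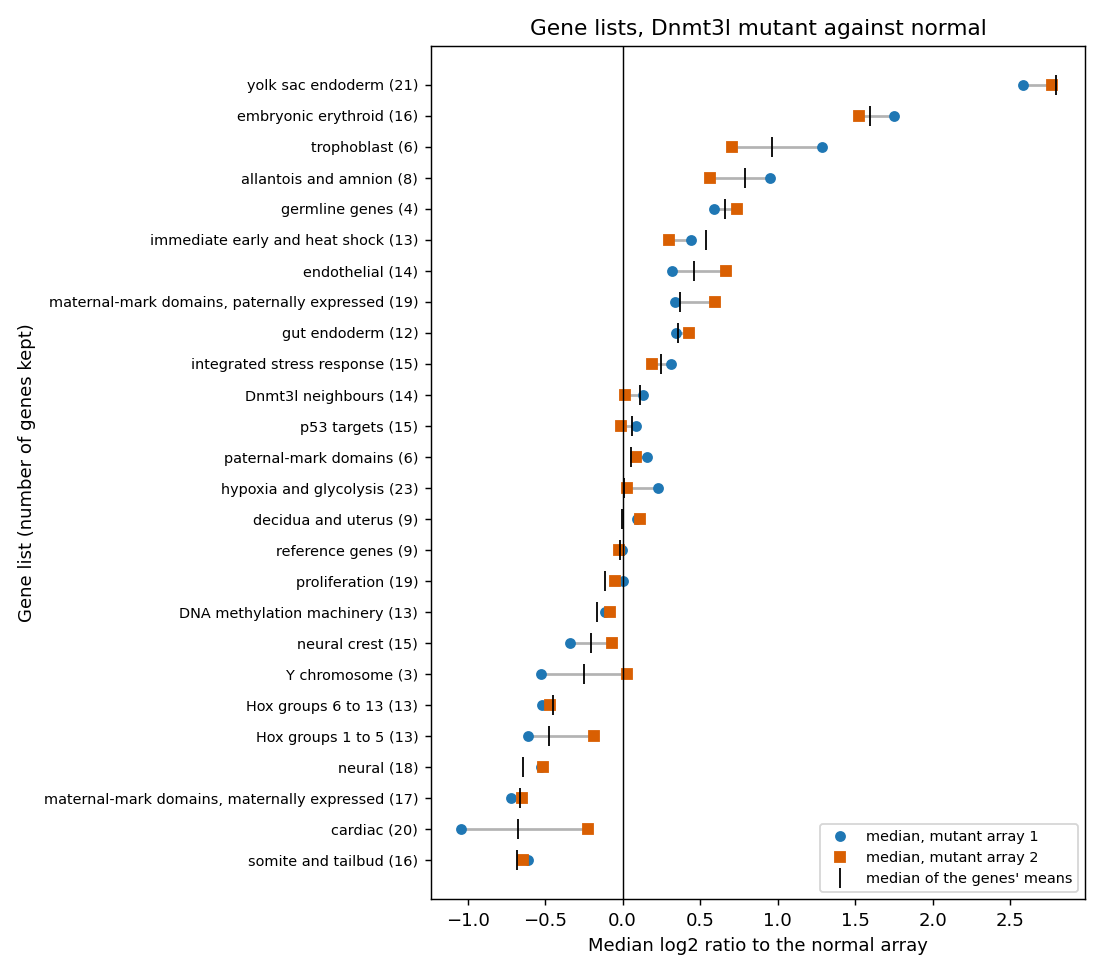
Median log2 ratio to the normal array for each fixed gene list with 3 or more kept genes (number of genes in brackets), with circles for mutant array 1, squares for mutant array 2 and ticks for the median of the genes' means over both arrays. Yolk sac endoderm (2.80) and embryonic erythroid (1.60) lie highest, and the cardiac (-0.67) and somite and tailbud (-0.68) lists lie lowest.

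Transcripts that report the sex makeup of the pools were measured because the labels give mixed sexes. Xist, the transcript of the inactive X chromosome, read 1296 in the normal pool and 2975 ± 337 (SD, n = 2) in the mutants, a log2 ratio of 1.17 (SE 0.21, adjusted p = 0.109 over all probe sets and 0.00179 adjusted over the list alone, which holds 1 gene). The mean of its probe sets gave a log2 ratio of 0.60. The 3 Y-linked genes measured had a median of -0.25 (-0.53 in mutant 1 and 0.03 in mutant 2, camera adjusted p = 0.219), with Eif2s3y at -1.03 and -0.44.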

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

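Of the tests in this part, those of a second yolk sac list and of unspliced RNA had their bounds written before their results were seen, and all others were chosen after the pattern was seen. The rules for the tests of embryo tissue and of blocks of probe set numbers were also rewritten after their values were seen: the first had used the smaller ratio alone, by which 0 of 54 genes fell as far as any of the 5 imprinted genes, H13 included, and the second had asked only whether named probe sets in the blocks read lower. The control feature AFFX-MURINE_b1 lies outside the comparisons above and was singled out because both mutant arrays exceeded the normal array. It read 6944 on the normal array and 14847 and 12910 on mutant arrays 1 and 2, so the smaller mutant signal was 1.86 times the normal signal. The companion control of the B2 repeat went the other way, with 24989 on the normal array and 22735 and 21653 on the mutant arrays. The count of called probe sets could be set against other splits of the 3 arrays into 1 against 2, but 3 splits are too few for a share under 0.05. The real split called 156 and the highest other 0 (limma), with 3664 probe sets at an unadjusted p under 0.05 in the real split against 987 and 630, so 1 of the 3 splits gave as many calls.

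Yolk sac endoderm genes were higher in both mutant arrays, with a median log2 ratio of 2.80. Array scaling is argued against, since the lowest median under 3 other normalizations was still 2.795. A candidate explanation is more yolk sac tissue in the mutant pools, which predicted that a second list of yolk sac genes, chosen after the pattern but before their values were seen, would be raised at least 1.5-fold. The median of their smaller log2 ratios was 2.04 over 17 genes, 14 were higher in both arrays and Apoh was lower, and the most abundant genes of the first list read 5888 against 19704 (Ttr), 4128 against 14544 (Afp) and 2746 against 17796 (Rbp4). No sorting step would have removed this tissue, and whether it was dissected away alike in all pools was not known. Of the 21 genes of the first list, 19 exceeded the array median in the normal pool too. A difference of the mutant embryos themselves, such as a smaller embryo proper or higher expression in yolk sac cells, stays open and untested.

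The maternally expressed genes Cdkn1c, Igf2r, Phlda2, Grb10 and H13 were at least 2-fold lower in both mutant arrays. These 5 were picked from the 17 kept by their own falls, so setting them against whole lists favours a difference. A smaller share of cardiac, neural and somite tissue is argued against as the whole cause for the first 4. Of 54 genes of those tissues, 0 had a mean log2 ratio, or a smaller of the 2 arrays' ratios, as low as any of them. In mutant 2 alone Cdx1, at -3.14, lay below Igf2r. A smaller share of other embryo tissues was not tested. Array scaling is argued against for all 5, because the shallowest log2 ratio under 3 other normalizations was -1.53. For H13 a smaller share of embryo tissue cannot be told apart, since 3 of the 54 (Hes7, Cdx1 and Fgf8) had a mean log2 ratio as low. Maternal tissue in the normal pool cannot be told apart for any of the 5. Of 9 decidua and uterus genes 1, Prl8a2, was 2-fold lower in both arrays, between the 0 set for excluding it and the 5 set for it. That count cannot decide the question, because the list's genes may not be confined to maternal tissue. Hoxa11 is also on a Hox list, and Igfbp4 read 11525 on the normal array and 12431 in the mutants. A loss of maternal marks would predict higher paternally expressed genes, and 14 of the 19 were higher in both arrays. Most of these rises were small, with a list median of 0.37 and 1 gene, Plagl1, at least 2-fold higher in both arrays. Among the 19 the noncoding Kcnq1ot1 read 0.34, while the noncoding Airn read -0.07 (-0.32 in mutant 1 and 0.19 in mutant 2). Neither passed adjusted over the list alone. That loss, which the design names, stays open as a biological explanation of the falls of the 5 genes above. The evidence rests on the first 4, since the median of the whole list differed from that of the 54 embryo tissue genes by 0.00363 (permutation p = 1).

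Probe sets that the annotation does not list made up 52.3% of those 2-fold lower in both arrays against 14% of all kept, and had a median log2 ratio of -0.29 against -0.03 for the others. Dimmer signal is argued against, since the mean difference within 5 bins of signal was -0.246. Less unspliced RNA in the mutants was tested on the dimmer probe sets of named genes, whose median difference from the brightest of the same gene was -0.0319 (95% bootstrap interval -0.0426 to -0.0201), and this met the bound of -0.05 set beforehand for excluding it. That bound was judged wrong only after the value was seen, because only 15.9% of those dimmer probe sets, against 57.1% of the unlisted ones, lie in the 6 of 23 blocks of probe set numbers rich in unlisted ones, and no file gives probe positions, so the explanation cannot be told apart here, although by the bound as first written it would be excluded. Those blocks, defined after looking at medians by block, are argued against as the whole cause within these arrays. Unlisted probe sets read lower than named ones inside them (-0.391 against -0.146) and outside (-0.179 against -0.0207). The mean difference was -0.201 (bootstrap interval -0.227 to -0.180). Named probe sets in the blocks also read -0.258 against the brightest of the same gene elsewhere. The bootstrap intervals of this paragraph resample probe sets of the same arrays and leave out variation between arrays or embryos. No biological explanation other than unspliced RNA was tested.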

How the results depend on the processing

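Every alternative here was fixed before the data were examined. No paired analysis was possible because only the mutant arrays carry replicate numbers and the normal group is 1 array. The 156 calls were 134 to 162 under other pseudocounts, 128 to 146 under other normalizations, 140 with the stricter filter and 143 with robust moderation, and 128 to 155 of them were shared. They were 0 higher and 0 lower without a filter, and 0 and 0 by eBayes without trend, where the lowest adjusted p was 0.0766 and 0.114; the cause was not tested beyond the larger number of probe sets (45037) without a filter. The 2-fold counts were 1066 higher and 824 lower without a filter, which adds dim probe sets, and 307 lower with the stricter filter. Leaving out each mutant array gave 1102 to 1118 higher and 1100 to 1581 lower, since a single array then had to pass. Values from 1 array against 1 have no test. Signal over background limits the dim probe sets, whose ratios depend most on the pseudocount.

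Camera with an estimated correlation and fry rest on 1 residual degree of freedom, so their results are imprecise. A list that lost its call by them rests on the preset correlation. The former gave yolk sac endoderm genes and paternally marked domains (median 0.0532) the same adjusted p of 0.476. Fry gave yolk sac endoderm genes and hypoxia genes (median 0.00699) the same adjusted p of 0.133. Such ties can arise from the adjustment over lists and do not show equal support. Other adjusted p-values of fry differed, up to 0.843 for the DNA methylation machinery. With an estimated correlation or by fry the list medians are by construction the same, and the calls were lost. This held for paternally expressed (0.371), maternally expressed (-0.664), erythroid (1.60), cardiac (-0.674), neural (-0.640), somite and tailbud (-0.680), Hox groups 1 to 5 (-0.477), Hox groups 6 to 13 (-0.446), yolk sac (2.795), trophoblast (0.964), allantois and amnion (0.787), endothelial (0.458), gut endoderm (0.357) and immediate early genes (0.540). Germline genes (0.664) were lost with an estimated correlation and kept by fry (adjusted p = 0.0433). Fewer genes passed the stricter filter, under which endothelial (0.345), gut endoderm (0.364) and immediate early genes (0.346) no longer passed and the germline median, over too few genes to test, was 2.73. Without a filter the germline median was 0.271 and that of Hox groups 6 to 13 was -0.183, which was -0.685 with the stricter filter. Trophoblast genes no longer passed without a filter (0.244), and hypoxia genes passed under quantile normalization (0.0352); the cause was not tested.

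Directions turned in small medians. Decidua and uterus genes read 0.0566, 0.0827 and 0.0442 under quantile normalization, cyclic loess and median centring, and reference genes 0.0706, 0.0416 and 0.0323. With the mean of probe sets, the reference median read 0.0942, and the single genes Plet1 (0.516) and Sdha (-0.00843) turned too, while Xist kept its direction at 0.598; the cause was not tested, beyond the other probe sets that enter the mean. Leaving out each mutant array, medians ranged from 0.339 to 0.598 (paternally expressed), -0.720 to -0.646 (maternally expressed), 0.0847 to 0.157 (paternal-mark domains), -0.116 to -0.0786 (methylation machinery), -0.528 to -0.512 (neural), -0.639 to -0.611 (somite and tailbud), -0.517 to -0.469 (Hox groups 6 to 13), -1.04 to -0.224 (cardiac), -0.612 to -0.186 (Hox groups 1 to 5), -0.342 to -0.0681 (neural crest), 0.193 to 0.315 (integrated stress response), 1.53 to 1.75 (erythroid), 0.708 to 1.29 (trophoblast), 0.567 to 0.949 (allantois and amnion), 0.322 to 0.670 (endothelial), 0.588 to 0.740 (germline), -0.527 to 0.0305 (Y chromosome), -0.0212 to -0.00638 (reference), 1.06 to 1.29 (Xist), 2.59 to 2.77 (yolk sac), 0.0963 to 0.111 (decidua and uterus), 0.347 to 0.427 (gut endoderm), -0.0460 to 0.00311 (proliferation), -0.00700 to 0.0858 (p53 targets), 0.0290 to 0.226 (hypoxia), 0.299 to 0.440 (immediate early) and 0.0133 to 0.133 (Dnmt3l neighbours). Of the 124 named genes, 104 kept direction and side of the threshold without a filter and 104 by eBayes without trend, where 20 lost the call in each. With the stricter filter 18 of them, Blvrb and Ces2b among these, were removed and had no value, and Ces2b had none with either smaller pseudocount. Values of single genes moved by over 1.5-fold with the mean of probe sets for Apob (2.48), Cldn2 (2.32), Grb10 (-2.22), Impact (0.416), H13 (-0.903), Rian (0.274), Pax3 (-0.652) and Plet1, with a pseudocount of 1 for Blvrb (4.70), Cdkn1c (-6.48), Prap1 (-3.61) and Wdr62 (-2.99), and with a doubled one for Ces2b (2.58). Leaving out each mutant array moved Mid1 (-3.56 to -2.28), Grb10 (-4.93 to -2.14), Peg10 (0.852 to 2.38), Hes7 (-2.81 to -1.25), Lum (0.714 to 2.43) and Postn (1.33 to 2.64) by as much. Of the 124 named genes, 107 kept direction and side of the threshold with the mean of probe sets and 15 newly passed. Under each remaining setting with a test, 3 at most lost the call.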

Other observations

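Of the lists that report on cell state, immediate early and heat shock genes passed camera with a preset correlation and the others did not. Tissue makeup differed in the same arrays, where yolk sac endoderm genes had a median log2 ratio of 2.80 and embryonic erythroid genes 1.60. Immediate early and heat shock genes, which rise fast with handling, had a median log2 ratio of 0.54 over 13 genes (camera adjusted p = 0.0214, and adjusted p = 0.476 with an estimated correlation), with Hspa1b at 1.35, Junb at 1.25, Klf6 at 0.91 and Egr1 at 0.68, and no gene passed alone. Hypoxia and glycolysis genes had a median of 0.00699 over 23 genes and a mean of 0.23 (camera adjusted p = 0.105). Adjusted over the list alone 2 of them rose, the oxidoreductase gene Ero1a (1.16, SE 0.19) and Ndrg1 (1.20, SE 0.25), while Vegfa (0.77) and Pfkp (0.75) did not pass. Integrated stress response genes (median 0.25 over 15, adjusted p = 0.105), p53 targets (0.06 over 15, adjusted p = 0.552) and proliferation genes (-0.11 over 19, adjusted p = 0.248) did not pass camera. Named members were Herpud1 (0.67), Asns (0.50), Chac1 (0.47) and Dnajb9 (0.33), then Trp53inp1 (0.73), Btg2 (0.50), Ccng1 (0.31) and Bbc3 (-0.27), then Ccnd1 (-0.59), Mcm5 (-0.45), Mcm7 (-0.35) and Cdc20 (-0.30), none of which passed.

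Germline genes were mostly below the filter, and 4 of 23 were kept. Their median log2 ratio was 0.66 (camera adjusted p = 0.0101, and adjusted p = 0.476 with an estimated correlation), and it was 0.27 over all 23 without the filter. Only Rhox5, an X-linked homeobox gene also expressed in placenta and yolk sac, rose, from 1250 to 8482 ± 196 (SD, n = 2), a log2 ratio of 2.73 (SE 0.17, adjusted p = 0.0111), while Stag3 (0.87) and Asz1 (0.46) did not pass. Genes of the DNA methylation machinery had a median of -0.16 over 13 genes (adjusted p = 0.463), with Mbd2 at 0.66, Tet1 at 0.35, Zfp57 at -0.30 and Uhrf1 at -0.37. Genes beside Dnmt3l, where DNA of another strain can remain after gene targeting, had a median of 0.11 over 14 genes (adjusted p = 0.359), with Pttg1ip at 0.93, Agpat3 at 0.83, Cstb at 0.46 and Trappc10 at 0.45. Reference genes had a median of -0.0138 over 9 genes (adjusted p = 0.599), which turned above 0 under other scalings of the arrays, with B2m at 1.05, Sdha at 0.46, Hprt at 0.37 and Gusb at -0.64.

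Of the hypotheses tested next, only the bound on a shift of the whole X chromosome was set before its result was seen, and the rules by which the tests were judged were rewritten after their values were seen. The first was that the parental classes of maternally marked domains moved apart, as a loss of maternal marks would predict. The classes are those of the fixed lists, and the allele expressed in these embryos was not tested. The median of the 19 paternally expressed genes exceeded that of the 17 maternally expressed genes by 1.035 on the log2 scale, which restates the list medians given above and is no further evidence. A comparison of the paternally expressed genes with the 54 cardiac, neural and somite genes was not used, because those 54 had fallen themselves (median -0.67). The maternally expressed genes lay 0.00363 from those 54 (permutation p = 1). The classes lay apart in the direction predicted, but a loss of marks cannot be told apart from tissue makeup by these medians, since the shift of the maternally expressed median could equally follow the lower embryo tissue genes. The paternally expressed median was 0.37 against -0.0187 for the 12913 kept genes, with 1 probe set per gene on both sides, and whether tissue makeup may account for that rise was not tested.

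The second hypothesis was that X-linked genes were over-represented among the highest genes. Of 12891 genes with a known chromosome, 431 were X-linked, and 25 of the 418 genes at least 2-fold higher in both mutant arrays were, which was 5.98% against 3.34% of all. This excess was noticed on the highest genes and those of the fixed lists, so it was tested again without every gene whose value had been seen by then. Of the 354 genes 2-fold higher that remained, 13 were X-linked, an odds ratio of 1.12 (95% interval 0.587 to 1.97, Fisher's exact test, two-sided p = 0.649), against 1.89 with all genes. An excess beyond the genes that prompted the test was therefore not found and cannot be told apart from none, since the interval includes both. In all, 3 X-linked genes were 2-fold lower. A small shift of the whole chromosome cannot be told apart from none either. The median of X-linked genes exceeded that of the others by 0.0323 (permutation p = 0.150), below the bound of 0.05. The bootstrap interval of -0.00251 to 0.0841 includes that bound. Permutation and bootstrap ran over genes of the same arrays and leave out variation between arrays or embryos. The X-linked genes that rose included S100g, 4933402E13Rik, Cldn2, Trap1a (3.07), Rhox5, Rhox6 (3.13), Rhox9 (2.47), Fmr1nb (2.74) and Mageb16 (2.42), of which those not named above were chosen after their values were seen. Only 4 of the 25 were on the fixed yolk sac, trophoblast, erythroid or allantois and amnion lists, but several are known from placenta or yolk sac, and the Rhox genes are neighbours and not independent. Whether the excess may follow the tissue makeup of the pools was not separated from an effect on the X chromosome.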
